A study of Mus musculus with 24 samples.

How the data were processed

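RNA was sequenced from mammary glands of 24 mice that carried an inducible transgene, labelled either Esr1, the oestrogen receptor alpha gene, or CYP19A1, the gene of aromatase, which makes oestrogens from androgens. Both transgenes are driven by a tetracycline-responsive operator and an rtTA activator under the MMTV promoter, per the labels. The samples formed 8 groups of 3: each line at 18 months of age after 6 months of induction, at 20 months after 8 months of induction, and at 20 months with a subcutaneous pellet of tamoxifen (25 mg over 60 days) or letrozole (2.5 mg over 60 days) carried for the last 2 months. Tamoxifen is an oestrogen receptor modulator and letrozole an aromatase inhibitor. The labels call the samples of a group biological replicates and give each a different animal number. The 20-month samples with neither drug carry the tag PLA in their sample descriptions, which the labels do not explain and which the 18-month samples lack. They are called untreated here because the labels give them no treatment, and whether they carried a pellet without drug is not given in the sources used here. There were no mice without a transgene among the samples.

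The deposited table held 55487 genes in TPM (transcripts per 1000000) for the 24 samples, each column summing to about 1000000, and the authors gave each value to 2 decimals. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.9a, RSEM 1.3.1 and the genome build mm10, without the role of each tool or the gene annotation, which are not given in the sources used here. Libraries were stranded total RNA libraries depleted of ribosomal RNA and primed at random, per the labels. TPM keeps no read depth, so the depth of each sample is unknown and no counting interval was given; the number of genes with at least 1 TPM ranged from 14410 to 17684 per sample. A value is a share of all the RNA in its library, so a few very abundant RNAs, or a change in the tissue sampled, shift every other value. Genes with near-identical copies (pseudogenes, ribosomal protein and histone families) can trade reads in an estimate of this kind, and small RNAs inside host genes are poorly separated from their hosts; both are reported as uncertain.

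Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend and robust settings), over the 19325 genes with at least 1 TPM in at least 3 samples. All 24 samples entered a single fit with 8 groups that shared an estimate of the spread. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and errors beside them are standard errors of the fit. The 16 comparisons were the lines against each other at 18 months, at 20 months without treatment and averaged over the 4 conditions, 20 against 18 months in each line, each drug against no treatment in each line and averaged, tamoxifen against letrozole in each line, and the differences between the lines in the effects of age, tamoxifen and letrozole (interaction terms). Comparisons that use the same untreated libraries share their chance variation.

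Gene lists, 32 in all with 450 members of which 449 were in the table, covered mammary epithelial subtypes, hormone response, proliferation, lipid and steroid metabolism, respiration, protein folding, immune and stromal cells, other tissues that a dissection can hold, and RNA quality. Each was tested with camera from limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists, and again with an estimated correlation and with fry, which tests whether a list moves on balance in 1 direction without comparing it with other genes. The values from fry are not reported here. Members were also adjusted over the list alone. A list score was the mean log2(TPM + 1) per sample of all its members in the table, including those too low to be tested singly. It was tested with limma over the lists, a test added after the data were seen, as was its repeat with each library left out.

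Comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, apart from the additions stated as such. The rule named, in each comparison, Esr1 and Cyp19a1; up to 12 higher and 12 lower genes with the largest changes among those that passed, without predicted gene symbols, immune receptor segments or genes under a mean of 2 TPM in the higher group, and with no overlap between the replicates (in averaged comparisons, the same sign in every condition); up to 4 members of each called list with the smallest p; and, where fewer than 5 genes passed, the 5 with the smallest p. Chance alone separates 3 libraries from 3 in 10% of genes. Other members of the fixed lists are named where they passed. The values of 1 list member are not reported here.

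The transgene levels were compared with a two-sided permutation test of 100000 resamples. Gene positions came from a table of the assembly GRCm38.p6, the same build as mm10, matched on the symbol; 16412 of the 19325 tested genes and 140 of the 144 genes named by size of change had one. The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold per comparison: it recovered 65 and 92 of them for letrozole in the Esr1 line, 93 and 100 for the averaged line comparison, and 35 and 90 for the interaction of letrozole and line. In these comparisons 7, 4 and 9 unchanged genes were called, and the changed genes were drawn from the more abundant ones. A shifted proliferation list was recovered by camera and 0 of 31 other lists were called in that simulation. The simulated genes varied independently of each other, so it does not show how camera behaves with correlated genes.

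Alternatives were a pseudocount of 0.1, no filter on low values, median-ratio scaling, rescaling without mitochondrial genes and the 50 most abundant genes, sample weights, the replicate number as a block, epithelial and B cell list scores as tissue covariates, a fit of only the compared groups, and leaving out each library in turn. After the data were seen, the muscle list score as a covariate and a fit without 3 libraries in doubt were added. Those 3 were Esr1 18-month replicate 1 and CYP19A1 18-month replicate 3, which held little muscle RNA, and Esr1 20-month untreated replicate 2, which held much ribosomal RNA. No sample was left out of the reported results. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.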

Results

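Whole mammary gland RNA from 24 aged mice was compared between 2 transgenic lines, labelled Esr1 and CYP19A1, with 3 mice per group. Each line was sampled at 18 months, at 20 months, and at 20 months after 2 months of tamoxifen or letrozole. The series asks how the 2 transgenes differ in the gland during reproductive senescence and whether the 2 anti-hormonal drugs act differently in each. Lines are named by their labels throughout, since the values below could not check the CYP19A1 transgene and did not bear out the Esr1 transgene. Esr1 did not differ detectably between the lines, and a human CYP19A1 sequence was not among the genes analysed. Gene levels are TPM with the SD over mice, and changes are log2 differences with the standard error of the fit.

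The glands differed in the tissue they held. The skeletal muscle list score was 5.82 ± 3.87 (SD, n = 3) in CYP19A1 and 7.18 ± 3.30 in Esr1 at 18 months. It was 10.21 ± 0.45 and 9.14 ± 0.96 at 20 months without treatment, and between 10.01 and 10.46 in the 4 treated groups. Acta1, skeletal muscle actin, stood at 6.51 TPM in CYP19A1 18-month replicate 3 and 38.34 TPM in Esr1 18-month replicate 1, and reached 7084.55 TPM in CYP19A1 20-month untreated replicate 3. Ribosomal RNA gene models took 31.2% of the TPM in Esr1 20-month untreated replicate 2, 3.60% in replicate 3 of the same group and 3.24% in Esr1 tamoxifen replicate 2, against a median of 0.0559% over the 24 libraries. Rn7s1 and Rn7s2, models of the signal recognition particle RNA, took 19.9% to 38.8%, mitochondrial genes 9.82% to 27.9% and protein-coding genes 29.7% to 39.7%.

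**Figure D1:**
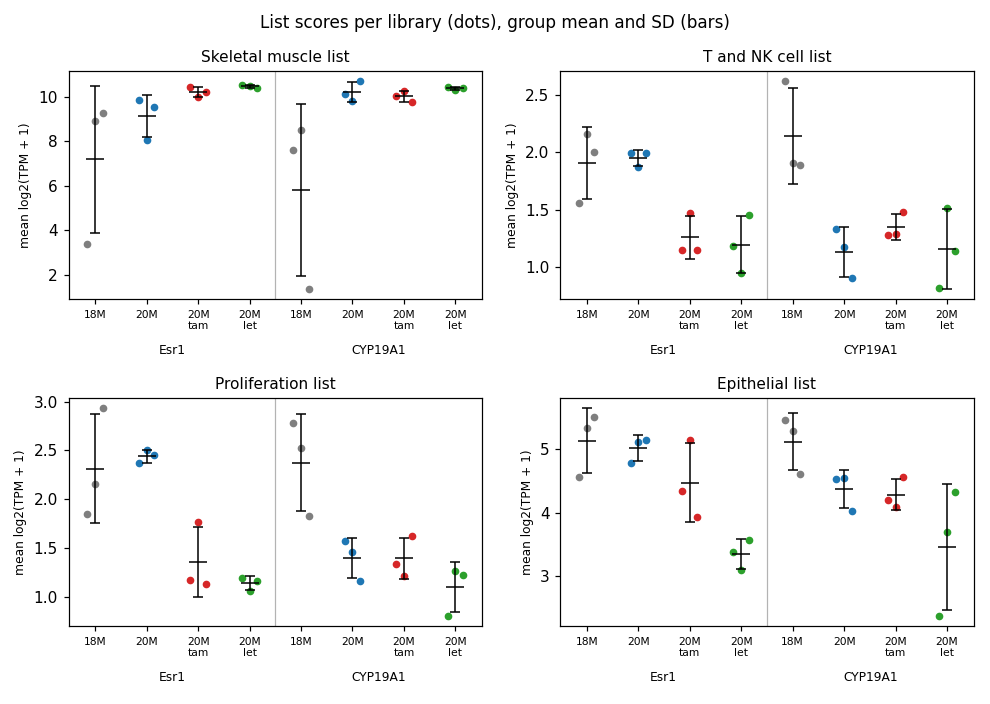
Mean log2(TPM + 1) of the skeletal muscle, T and NK cell, proliferation and epithelial lists in each library (points), with the mean and SD of each group of 3. The muscle score varied most at 18 months (5.82 ± 3.87 in CYP19A1), and the proliferation score was 2.44 ± 0.07 in untreated Esr1 glands at 20 months.

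Esr1 (chromosome 10, 4611989 to 5005633, ENSMUSG00000019768.16) did not differ detectably between the lines. Its level was 14.5 ± 2.64 TPM (SD, n = 12) in the Esr1 line and 15.1 ± 2.38 TPM (n = 12) in the CYP19A1 line. The log2 difference was 0.07 (two-sided permutation p = 0.60), and -0.017 without Esr1 20-month untreated replicate 2. Its adjusted p was 0.81 in the averaged limma comparison, and it passed in none of the 16 comparisons. The mouse gene Cyp19a1 was listed above 0 in 2 of 12 Esr1 libraries, at most at 0.15 TPM, and in 8 of 12 CYP19A1 libraries, at most at 0.27 TPM. These Cyp19a1 values were too low to be tested. A human CYP19A1 sequence was not among the genes analysed here, so that transgene could not be checked. Esr1 was also present in the CYP19A1 line, and no mice without a transgene were among the samples. Whether this gene model counts the Esr1 transgene is not given in the sources used here, so the lack of a difference does not show that it was absent.

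Averaged over the 4 conditions, a set of genes separated the lines by large and steady amounts. Ifi202b, an interferon-inducible gene (chromosome 1, 173962569 to 173982844), stood at 24.6 ± 3.39 TPM (n = 12) in CYP19A1 and 0.506 ± 0.285 TPM (n = 12) in Esr1 glands, a difference of 4.10 ± 0.10. Gchfr, a regulator of tetrahydrobiopterin synthesis (chromosome 2, 119167788 to 119172389), stood at 9.27 ± 3.45 against 0.237 ± 0.218 TPM. Kpna2, a nuclear import receptor (chromosome 11, 106988629 to 106999525), was lower in CYP19A1 glands by -2.49 ± 0.11. Mndal, another interferon-inducible gene, was lower by -2.19 ± 0.17, and Rps18, a ribosomal protein gene, by -1.79 ± 0.12. These 5 genes had adjusted p from 1.3e-17 to 9.9e-09 in limma. As a ribosomal protein gene Rps18 can trade reads with near-identical copies, so its value is uncertain, as are those of the pseudogenes that follow. The pseudogene Rpl15-ps3 was listed at 0 in all 12 CYP19A1 libraries and at 58.8 ± 25.5 TPM in the Esr1 line. The pseudogenes Rpl35a-ps2, Rpl35a-ps3, Rpl35a-ps4 and Rpl35a-ps6 shared the same values, 59.1 ± 12.3 TPM in the CYP19A1 line against 1.97 ± 1.59 TPM in the Esr1 line, so that they cannot be told apart.

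Some genes of fatty acid synthesis, oxidative phosphorylation and endothelium were higher in the CYP19A1 line over the same average, while no score of these lists passed (0.66 ± 0.19, 0.30 ± 0.11 and 0.34 ± 0.11, limma adjusted p = 0.056, 0.082 and 0.069). Of 15 genes of fatty acid synthesis 7 were higher (11 adjusted over the list alone), among them Fasn, fatty acid synthase, by 1.37 ± 0.28 and Acaca, acetyl-CoA carboxylase, by 1.12 ± 0.23 (limma adjusted p = 0.0031 and 0.0039). Their list had adjusted p = 4.9e-07 in camera from limma, and adjusted p = 0.71 with an estimated correlation. Of 18 genes of oxidative phosphorylation 5 were higher (16 adjusted over the list alone), including Cox5a by 0.45 ± 0.10. Of 11 endothelial genes 4 were higher (8 adjusted over the list alone), including Emcn by 0.60 ± 0.13 and Kdr, a VEGF receptor, by 0.51 ± 0.11. Cfd, the adipocyte-secreted complement factor D, was higher by 1.19 ± 0.22, with 2 others of 13 white adipocyte genes. Of 12 basal and myoepithelial genes 5 were lower (8 adjusted over the list alone), including Krt14 by -0.72 ± 0.17 and Cnn1 by -0.75 ± 0.17, and 1 was higher. H2-Eb1, an MHC class II gene, was lower by -1.48 ± 0.39 with 2 others of 10. For each of these 5 further lists camera from limma gave adjusted p = 0.71 with an estimated correlation.

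In that comparison 765 genes were higher and 639 lower in CYP19A1 glands (1404 in limma at adjusted p under 0.05, and 3623 at unadjusted p under 0.05). Of the 1404 genes, 1231 had the same sign in all 4 conditions, 135 had no overlap between the 12 and 12 libraries, and 191 were pseudogenes. After rescaling without the most abundant genes the split was 978 higher and 1225 lower, and with the tissue covariates 2584 and 616. With 1 library left out, the higher fatty acid synthesis genes numbered between 4 (without Esr1 20-month untreated replicate 2) and 10 (without CYP19A1 letrozole replicate 3). The range was 3 (without Esr1 tamoxifen replicate 2) to 13 (without Esr1 20-month untreated replicate 1) for oxidative phosphorylation and 3 (without Esr1 letrozole replicate 1) to 9 (without Esr1 20-month untreated replicate 1) for endothelial genes. Lower basal genes numbered 3 without Esr1 18-month replicate 2, and lower MHC class II genes 0 in limma without Esr1 letrozole replicate 1. H2-Eb1 lost its call without any of Esr1 tamoxifen replicate 3, Esr1 letrozole replicate 1, CYP19A1 18-month replicate 3, CYP19A1 tamoxifen replicate 2 or CYP19A1 letrozole replicate 3 (limma adjusted p up to 0.056 over all alternatives).

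At 18 months Ifi202b was higher in CYP19A1 than in Esr1 glands by 3.87 ± 0.20 and Gchfr by 3.22 ± 0.20, while Kpna2 was lower by -2.68 ± 0.21 (limma adjusted p from 4.4e-11 to 3.5e-08). Cdsn, corneodesmosin, an adhesion protein of cornified epithelium, stood at 0.360 ± 0.0964 TPM (n = 3) against 6.15 ± 2.07 TPM, a difference of -2.36 ± 0.37. Thbd, the endothelial anticoagulant receptor thrombomodulin, was lower by -1.93 ± 0.39 (limma adjusted p = 0.010). The small nucleolar RNA Snora68 stood at 103 ± 41.4 against 5.77 ± 5.04 TPM, which is uncertain for a small RNA. Of the 15 genes of fatty acid synthesis 0 passed over all genes in limma, but 8 were higher adjusted over the list alone. Their score differed by 1.01 ± 0.37, and camera from limma gave adjusted p = 5.8e-07, or adjusted p = 0.95 with an estimated correlation. The muscle score differed by -1.36 ± 1.39 beside these groups.

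Altogether 173 genes were higher and 89 lower in CYP19A1 glands at 18 months (262 in limma, and 1619 at unadjusted p under 0.05), and 159 higher and 150 lower after rescaling without the most abundant genes. Thbd lost its call without Esr1 18-month replicate 1 or without CYP19A1 18-month replicate 1 or 2, with limma adjusted p up to 0.062 over all the alternatives run. Snora68 lost its call without Esr1 18-month replicate 3 or CYP19A1 18-month replicate 1, with a pseudocount of 0.1 or with only the compared groups fitted (limma adjusted p up to 0.24).

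At 20 months without treatment, proliferation and T cell genes were lower in CYP19A1 than in Esr1 glands. Gjb6, a gap junction gene, stood at 0.223 ± 0.235 TPM (n = 3) against 43.7 ± 29.6 TPM, a difference of -5.02 ± 0.80. Rspo1, a Wnt agonist, stood at 2.63 ± 0.961 against 46.6 ± 18.8 TPM, and Csn1s1, a casein, at 260 ± 214 against 3470 ± 2850 TPM (limma adjusted p = 0.0012, 0.0091 and 0.036 for the 3 genes). Of 20 proliferation genes 11 were lower (19 adjusted over the list alone), among them Mki67 by -1.97 ± 0.40 and Birc5 by -1.43 ± 0.28. The proliferation score differed by -1.04 ± 0.25 (limma adjusted p = 0.016), and camera from limma gave the list adjusted p = 4.1e-14, or adjusted p = 0.54 with an estimated correlation. Of 15 T and NK cell genes 7 were lower (11 adjusted over the list alone), including Cd3d, a chain of the T cell receptor complex, by -1.10 ± 0.24 and the chemokine Ccl5 by -1.64 ± 0.35. Their score differed by -0.82 ± 0.21 (limma adjusted p = 0.016, and adjusted p = 0.54 with an estimated correlation in camera). Beside these groups the scores differed by -0.76 ± 0.30 for lymph node stroma, -0.65 ± 0.39 for epithelium, 1.07 ± 1.39 for muscle and 0.65 ± 0.28 for mitochondrially encoded genes (limma adjusted p from 0.12 to 0.62).

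Hormone-sensing luminal genes went both ways in that comparison. Prom1 (1.59 ± 0.31), Ly6a (1.22 ± 0.30) and Pgr, the progesterone receptor (1.44 ± 0.39), were higher in CYP19A1 glands. Calca, calcitonin (-4.01 ± 0.96), and Tnfsf11, the RANK ligand through which progesterone signals to neighbouring cells (-2.42 ± 0.56), were lower (limma adjusted p from 0.0049 to 0.039). Adjusted over the list alone, 5 of the 12 were higher and 2 lower. Of 18 oxidative phosphorylation genes 4 were higher (14 adjusted over the list alone), including Cox5a by 0.84. Of 15 milk protein genes Csn1s1 and Folr1 were lower (8 adjusted over the list alone). Camera from limma gave these lists adjusted p = 1.3e-08 and 1.7e-06, and adjusted p = 0.72 with an estimated correlation for both.

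There were 409 genes higher and 610 lower in that comparison (1019 in limma, and 4176 at unadjusted p under 0.05), 1315 and 1539 after median-ratio scaling, 1125 and 1417 after rescaling without the most abundant genes, and 1352 and 536 with the tissue covariates, where most were higher. The proliferation and T and NK cell scores lost their calls without Esr1 or CYP19A1 replicate 3 (limma adjusted p up to 0.12). The count was 1941 without Esr1 replicate 1, 602 without Esr1 replicate 2, and 511, 564 and 256 without CYP19A1 replicates 1, 2 and 3. Without CYP19A1 replicate 3, 1 of the 20 proliferation genes and 0 of the 15 T and NK cell genes were lower over all genes in limma, and Mki67, Rspo1, Cd3d and Ccl5 lost their calls (limma adjusted p up to 0.064). Without Esr1 replicate 2, 1 hormone-sensing gene was higher and 0 oxidative phosphorylation genes passed in limma, against 14 without Esr1 replicate 1. Csn1s1, Folr1, Ly6a, Pgr, Calca and Tnfsf11 lost their calls without Esr1 replicate 2 or CYP19A1 replicate 2 or 3, all of these but Csn1s1 without CYP19A1 replicate 1, and all but Ly6a and Pgr without Esr1 replicate 3 (limma adjusted p up to 0.23). Cox5a lost its call without Esr1 replicate 2 or CYP19A1 replicate 1 or 3 or with only the compared groups fitted (limma adjusted p up to 0.20), while Gjb6, Birc5 and Prom1 kept theirs under every alternative.

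Between 18 and 20 months, a span that also differs in induction time and in the sample tag PLA, few differences passed in the Esr1 line. The predicted gene Gm44340, named after its value was seen, was lower and alone passed in limma (0 higher and 1 lower, with 1214 at unadjusted p under 0.05). Klk1b22, a kallikrein, stood at 0.0533 ± 0.0924 TPM at 20 months against 3.28 ± 0.391 TPM (n = 3 each), a difference of -2.02 ± 0.35 that missed the threshold (limma adjusted p = 0.066). Adjusted over the list alone, 5 of 5 erythroid genes and 4 of 14 immediate early genes were lower at 20 months. Their scores differed by -0.91 ± 0.33 and -0.44 ± 0.16 (limma adjusted p = 0.19 for both, and adjusted p = 0.33 with an estimated correlation in camera). The muscle score differed by 1.96 ± 1.39. The median of all genes was -0.136 log2 in this comparison and 0.00917 after median-ratio scaling. The count was 0 without Esr1 18-month replicate 2, 17 without 20-month replicate 1, and 2 without 18-month or 20-month replicate 3.

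In the CYP19A1 line, muscle genes rose and proliferation and T cell genes fell between 18 and 20 months. Myh1, a fast myosin heavy chain (chromosome 11, 67200102 to 67224577), stood at 607 ± 256 against 77.6 ± 81.4 TPM (n = 3 each), and Mb, myoglobin, rose by 4.31 ± 1.11. The muscle score rose by 4.39 ± 1.39 (limma adjusted p = 0.040, and adjusted p = 0.39 with an estimated correlation in camera), with 2 of 12 members past the threshold and 12 adjusted over the list alone. Without 18-month replicate 3, whose muscle score was 1.38 against 7.59 and 8.49 in the others, it differed by 2.17 ± 1.07 (limma adjusted p = 0.21). Of 15 T and NK cell genes 11 fell (12 adjusted over the list alone), with Ccl5 at -1.99 ± 0.35 and Cd8b1 at -1.38 ± 0.24. The T and NK cell score was 1.13 ± 0.22 at 20 months against 2.14 ± 0.41 at 18 months (limma adjusted p = 0.0040, and adjusted p = 0.39 with an estimated correlation in camera). Of 20 proliferation genes 14 fell (19 adjusted over the list alone), with Mcm5, a replicative helicase subunit, at -1.56 ± 0.35 and Birc5 at -1.19 ± 0.28. The proliferation score fell by 0.98 ± 0.25 (limma adjusted p = 0.017, and adjusted p = 0.61 with an estimated correlation in camera). Calca fell by 3.93 ± 0.96, Tnfsf11 by -2.30 ± 0.56 and Muc15, a mucin, by -2.75 ± 0.74 (limma adjusted p from 0.022 to 0.030).

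In the same comparison the brown adipocyte list genes Cpt1b (2.85 ± 0.65), Cox7a1 (2.45 ± 0.58) and Ppara (0.80 ± 0.24) rose, 3 of 10 with 6 adjusted over the list alone. Their score rose by 1.27 ± 0.38 (limma adjusted p = 0.036, and adjusted p = 0.29 with an estimated correlation in camera). Cpt1b and Cox7a1 are also abundant in muscle, and with the muscle score as a covariate, added after seeing the data, 1 brown adipocyte gene passed. The unfolded protein response genes Sdf2l1, Manf, Hspa5, Pdia4, Pdia6 and Hyou1 fell, 6 of 14 with 10 adjusted over the list alone (camera from limma, adjusted p = 0.014, and adjusted p = 0.87 with an estimated correlation). After median-ratio scaling 0 of them passed in limma.

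Altogether 581 genes rose and 1246 fell with age in the CYP19A1 line (1827 in limma, and 5666 at unadjusted p under 0.05). The median of all genes was -0.225 log2, and -0.0243 after median-ratio scaling, which gave 1335 higher and 387 lower genes, while rescaling without the most abundant genes gave 1258 and 412. Beside these changes the epithelial score differed by -0.74 ± 0.39 (limma adjusted p = 0.14), and with the epithelial and B cell scores as covariates 2 proliferation and 6 T and NK cell genes passed. With no filter 6 proliferation and 7 T and NK cell genes passed, and 8 and 6 proliferation genes after the 2 scalings. The muscle score also lost its call without any 20-month replicate, the proliferation score without 18-month replicate 1 or 2 or 20-month replicate 3, and the brown adipocyte score without 18-month replicate 2 or 3 or 20-month replicate 1 or 3 (limma adjusted p up to 0.21). The T and NK cell and proliferation scores stayed lower under both scalings (-0.82 ± 0.17 and -0.79 ± 0.23, then -1.07 ± 0.24 and -1.02 ± 0.30). The count was 2 without 20-month replicate 3, 596 without 20-month replicate 2, 1163 without 20-month replicate 1, 126 without 18-month replicate 1 and 754 without 18-month replicate 2. Without 20-month replicate 3 the call of every gene named for this comparison ended (limma adjusted p up to 0.30 over the alternatives), and 0 T and NK cell genes passed in limma. Without 18-month replicate 1, 0 proliferation genes passed in limma, and of the genes named Ccl5, Cd8b1 and Cpt1b kept their calls.

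The change with age was not shown to differ between the lines beyond a single gene. Gstp-ps, a glutathione S-transferase pseudogene (chromosome 1, 192073736 to 192076444), had an interaction of 1.86 ± 0.28 (limma adjusted p = 0.031, with 1652 genes at unadjusted p under 0.05). The T and NK cell score had an interaction of -1.05 ± 0.30 and the proliferation score of -1.10 ± 0.36 (limma adjusted p = 0.070 and 0.098, and camera adjusted p = 0.57 with an estimated correlation for both). The count was 47 without CYP19A1 18-month replicate 3, 3 and 2 without Esr1 18-month replicates 1 and 3, 925 with sample weights and 83 with the muscle covariate. It was 0 in limma without CYP19A1 18-month replicate 1 or 2 or CYP19A1 20-month replicate 2 or 3, and Gstp-ps lost its call there and without Esr1 18-month replicate 2 (limma adjusted p up to 0.53 over the alternatives).

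**Figure D2:**
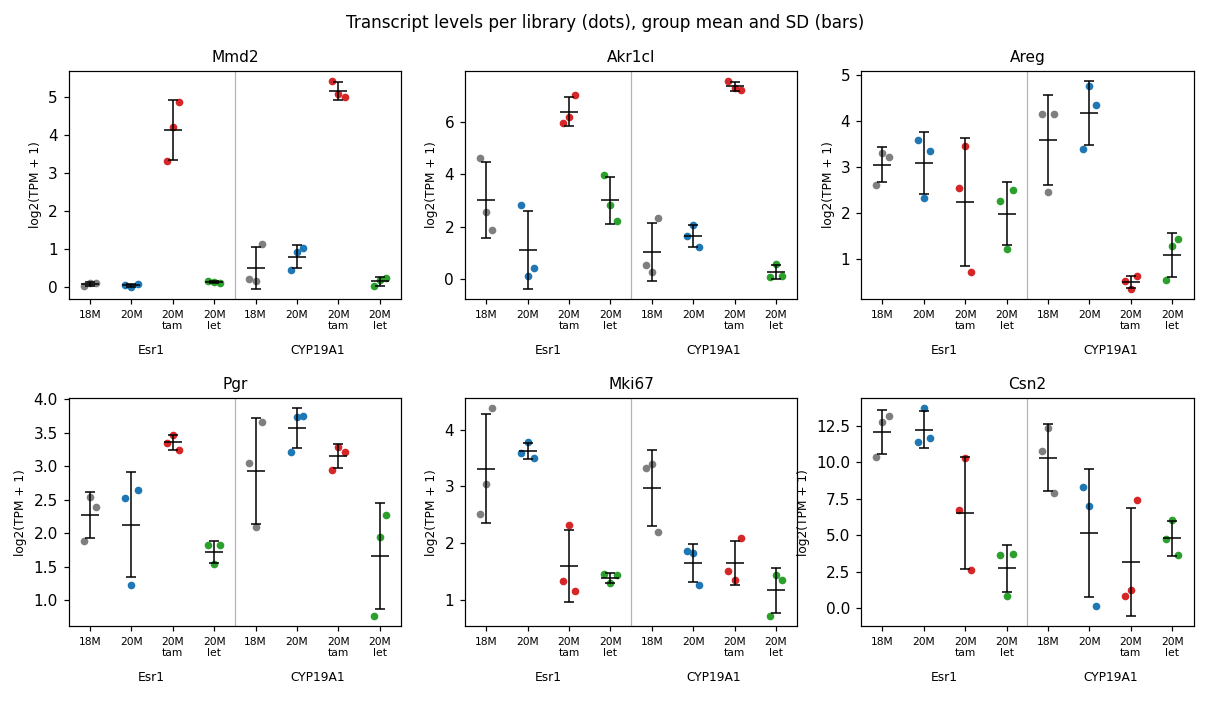
TPM of Mmd2, Akr1cl, Areg, Pgr, Mki67 and Csn2 in each library, as log2(TPM + 1), with the mean and SD of each group of 3. Mmd2 and Akr1cl stood apart in the tamoxifen groups of both lines (Mmd2 at 18.4 ± 9.85 and 35.3 ± 5.93 TPM), and Csn2 was lowest in letrozole glands of the Esr1 line on average (8.04 ± 6.30 TPM).

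Tamoxifen raised a small set of genes steeply in the Esr1 line and lowered proliferation genes. Akr1cl, an aldo-keto reductase family gene (chromosome 1, 65013078 to 65032759), stood at 88.5 ± 37.1 against 2.20 ± 3.44 TPM (n = 3 each), a rise of 5.28 ± 0.72. Mmd2 (chromosome 5, 142563480 to 142608936) stood at 18.4 ± 9.85 against 0.0400 ± 0.0265 TPM, a rise of 4.09 ± 0.28 (limma adjusted p = 0.0022 and 8.4e-08). Pcp4, a calmodulin-binding protein gene, rose by 3.46 ± 0.50 and Thbs2, a matrix thrombospondin, by 2.72 ± 0.52. Gjb6 (-4.05 ± 0.80), Rspo1 (-3.71 ± 0.75) and Muc15 (-3.36 ± 0.74) fell (limma adjusted p from 0.021 to 0.033). Of 20 proliferation genes 7 fell (19 adjusted over the list alone), with Mki67 at -2.02 ± 0.40 and Cdk1 at -1.52 ± 0.30. Their score fell by 1.08 ± 0.25 (limma adjusted p = 0.014, and adjusted p = 0.49 with an estimated correlation in camera). Of 15 T and NK cell genes 2 fell and 10 were lower adjusted over the list alone, and their score differed by -0.69 ± 0.21 (limma adjusted p = 0.059, and adjusted p = 0.49 with an estimated correlation in camera). Beside these groups the epithelial score differed by -0.55 ± 0.39, the milk protein score by -2.03 ± 0.90 and the muscle score by 1.08 ± 1.39 (limma adjusted p from 0.24 to 0.57). The 18-month groups (SD 3.87 and 3.30) widen the error of the muscle score. Its values were 9.85, 8.05 and 9.52 without treatment and 10.44, 9.98 and 10.23 with tamoxifen, without overlap.

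In that comparison 137 genes rose and 162 fell (299 in limma, and 3556 at unadjusted p under 0.05), 772 and 1109 after median-ratio scaling, 778 and 785 after rescaling without the most abundant genes, and 613 and 253 with the tissue covariates. The proliferation score lost its call without untreated replicate 2 or tamoxifen replicate 1 or 3 (limma adjusted p up to 0.10). Only 6 passed when the compared groups alone were fitted, where Mmd2 and Pcp4 passed and Akr1cl did not (limma adjusted p = 0.14, the highest over its alternatives). The count was 1188 and 52 without untreated replicates 1 and 2, and 164, 453 and 42 without tamoxifen replicates 1, 2 and 3. Thbs2, Gjb6, Rspo1, Muc15, Mki67 and Cdk1 lost their calls without untreated replicate 2 or tamoxifen replicate 3, and the last 3 also without tamoxifen replicate 1 (limma adjusted p up to 0.44 over the alternatives). Without untreated replicate 2, 0 proliferation genes passed in limma.

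In the CYP19A1 line tamoxifen raised Akr1cl to 165 ± 21.0 from 2.25 ± 0.933 TPM (5.71 ± 0.72) and Mmd2 to 35.3 ± 5.93 from 0.780 ± 0.352 TPM (4.36 ± 0.28, n = 3 each). Nmu, the neuropeptide neuromedin U, rose by 3.53 ± 0.35, Krt4, a keratin of stratified epithelia, by 3.23 ± 0.37 and Thbs1, a thrombospondin, by 2.61 ± 0.34 (limma adjusted p from 2.6e-08 to 0.00057 for these 5). Areg, the oestrogen-induced growth factor amphiregulin (chromosome 5, 91139599 to 91148432), fell by 3.67 ± 0.59, from 18.4 ± 8.35 to 0.420 ± 0.131 TPM (limma adjusted p = 0.0078). It was the only member to pass among 12 hormone-sensing luminal genes and among 21 tested oestrogen-responsive genes (1 of each adjusted over the list alone). Camera from limma gave the hormone-sensing list adjusted p = 2.1e-06, or adjusted p = 0.60 with an estimated correlation.

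In all, 22 genes rose and 9 fell with tamoxifen in the CYP19A1 line (31 in limma, and 846 at unadjusted p under 0.05), and 26 and 17 after median-ratio scaling. The count was 15 and 16 without untreated replicates 2 and 3 and 18 and 15 without tamoxifen replicates 1 and 2. Areg lost its call without untreated replicate 2 or 3 or tamoxifen replicate 2 (limma adjusted p up to 0.075 over the alternatives run), while Akr1cl, Mmd2, Nmu, Krt4 and Thbs1 kept theirs under every alternative.

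The genes that rose with tamoxifen overlapped between the lines. Of the 22 genes that rose in the CYP19A1 line 16 were among the 137 that rose in the Esr1 line, with no library shared. Independent lists would share 0.16, but these lists used the same estimate of the spread. The shared genes that rose included Akr1cl, Mmd2, Krt4 and Fam78b. Of the 162 genes that fell in the Esr1 line 67 had the same sign in the CYP19A1 line. Among its 9 falling genes 1 was shared, against 0.075 for independent lists. Over all genes the correlation of the tamoxifen changes between the lines was 0.15. Averaged over the lines, Aqp5, an aquaporin of secretory glands, rose by 2.65 ± 0.44, Oxtr, the oxytocin receptor, by 2.29 ± 0.41 and Agt, angiotensinogen, by 2.28 ± 0.40, and Areg fell by 2.26 ± 0.42 (limma adjusted p from 0.0053 to 0.012). Of 20 proliferation genes 0 passed in limma in the average, and 15 were lower adjusted over the list alone (score -0.54 ± 0.18, limma adjusted p = 0.23, and camera adjusted p = 0.81 with an estimated correlation). The proliferation score was 1.36 ± 0.36 with tamoxifen against 2.44 ± 0.07 without in the Esr1 line (SD). In the CYP19A1 line it was 1.40 ± 0.21 both with and without tamoxifen, so the average reflects the Esr1 line.

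The average gave 86 higher and 9 lower genes (95 in limma, and 2408 at unadjusted p under 0.05), 150 and 69 after median-ratio scaling and 141 and 44 after rescaling without the most abundant genes. The count was 437 without Esr1 untreated replicate 1 and 174 without Esr1 tamoxifen replicate 1. Aqp5, Agt and Areg lost their calls when only the compared groups were fitted (limma adjusted p = 0.087, 0.076 and 0.066, each the highest over its alternatives).

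The effect of tamoxifen was not shown to differ between the lines. The interaction gave 0 genes in limma (2021 at unadjusted p under 0.05). Apoc1, an apolipoprotein gene, came closest at 1.77 ± 0.31 (limma adjusted p = 0.076), and Areg had an interaction of -2.83 ± 0.84 (limma adjusted p = 0.31). The proliferation score had an interaction of 1.08 ± 0.36 and the T and NK cell score of 0.91 ± 0.30 (limma adjusted p = 0.12 for both, and camera adjusted p = 0.66 with an estimated correlation). The count was 6 without Esr1 tamoxifen replicate 3 and 2 without CYP19A1 untreated replicate 1, and it was 624 with sample weights, 43 with the muscle covariate and 8 after median-ratio scaling.

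**Figure D3:**
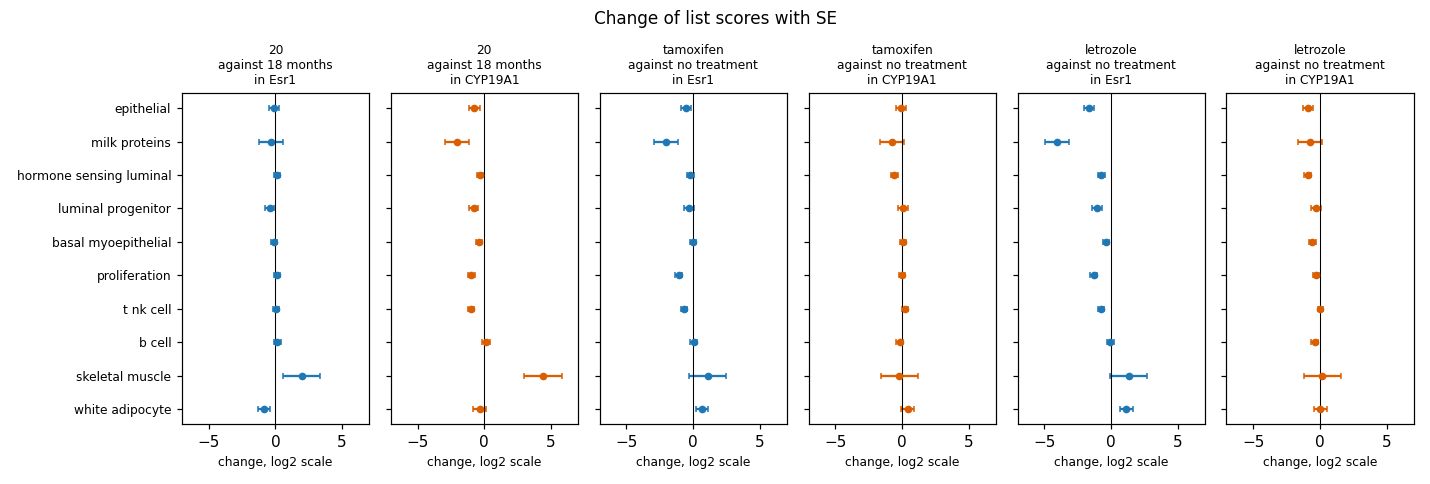
Change of 10 list scores, in mean log2(TPM + 1) with the standard error of the fit, for age, tamoxifen and letrozole in each line. The milk protein score fell by 4.04 ± 0.90 with letrozole in the Esr1 line, the lowest value drawn, and the muscle score rose by 4.39 ± 1.39 with age in the CYP19A1 line.

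Letrozole in the Esr1 line lowered milk protein, epithelial and proliferation genes together. Csn2, beta-casein (chromosome 5, 87692619 to 87699429), stood at 8.04 ± 6.30 against 6370 ± 5940 TPM (n = 3 each), a fall of -9.52 ± 2.12. Csn1s2a, Wap and Lalba, also milk protein genes, fell by -9.76 ± 2.07, -7.25 ± 1.94 and -5.13 ± 1.17 (limma adjusted p from 0.010 to 0.028). Of 15 milk protein genes 11 fell (13 adjusted over the list alone), and their score fell by 4.04 ± 0.90 (limma adjusted p = 0.0041). Of 14 epithelial genes 11 fell (12 adjusted over the list alone), among them Krt8 by -1.77 ± 0.41 and Cdh1, E-cadherin, by -1.89 ± 0.39, with the score at -1.67 ± 0.39 (limma adjusted p = 0.0046). Of 20 proliferation genes 18 fell (20 adjusted over the list alone), among them Mki67 by -2.22 ± 0.40 and Ccna2 by -1.76 ± 0.30, with the score at -1.30 ± 0.25 (limma adjusted p = 0.0019). Camera from limma gave these 3 lists adjusted p = 0.57 with an estimated correlation. Of 15 T and NK cell genes 7 fell (10 adjusted over the list alone), with Trac at -1.37 ± 0.29 and Cd3d at -1.07 ± 0.24 and the score at -0.76 ± 0.21 (limma adjusted p = 0.015, and camera adjusted p = 0.63 with an estimated correlation). The muscle score differed by 1.32 ± 1.39 beside these groups, with an error that the 18-month groups (SD 3.87 and 3.30) widen. Its values were 9.85, 8.05 and 9.52 without treatment and 10.51, 10.49 and 10.39 with letrozole, without overlap. The mitochondrially encoded score was 10.43 ± 0.03 against 9.71 ± 0.65 (limma adjusted p = 0.068, and camera adjusted p = 0.63 with an estimated correlation), with mt-Atp6, mt-Co3 and mt-Nd3 higher among 13, between 0 (without untreated replicate 2) and 8 (without untreated replicate 1) with a library left out.

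Luminal progenitor genes Rspo1 (-4.26 ± 0.75), Elf5, the transcription factor of alveolar differentiation (-2.93 ± 0.59), Csn3 and Trf fell among 12 (4 adjusted over the list alone). Hormone-sensing genes Gata3 (-1.52 ± 0.31), Calca and Tnfsf11 fell among 12 (3 lower and 1 higher adjusted over the list alone). These scores fell by 1.07 ± 0.36 and 0.72 ± 0.24 (limma adjusted p = 0.035 for both, and camera adjusted p = 0.70 with an estimated correlation). Lymph node stroma genes Glycam1, Madcam1 and Clu fell among 9 (4 adjusted over the list alone), and Glycam1 and Clu are also made by mammary epithelium. Their score fell by 0.91 ± 0.30 (limma adjusted p = 0.035, and camera adjusted p = 0.70 with an estimated correlation). Aldh1a1, a retinal dehydrogenase, rose by 2.16 ± 0.39, and the immediate early genes Nr4a1 (1.36 ± 0.29), Dusp1 (1.24 ± 0.30), Klf4 and Zfp36 rose among 14 (5 higher and 1 lower adjusted over the list alone). Rps2 and Rpl34 rose by 4.42 ± 0.75 and 3.90 ± 0.63, but these ribosomal protein genes have many processed copies and their values are uncertain.

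With letrozole 550 genes rose and 1122 fell in the Esr1 line (1672 in limma, and 5006 at unadjusted p under 0.05), and 1822 rose and 2289 fell after median-ratio scaling. With epithelial and B cell scores as covariates 0 passed in limma. That fit cannot decide on tissue share, since the epithelial score itself separated the groups. Its values were 4.79, 5.12 and 5.15 without treatment and 3.39, 3.10 and 3.57 with letrozole. The T and NK cell score lost its call without letrozole replicate 2, and so did the luminal progenitor score without any library but letrozole replicate 3. The hormone-sensing score lost its call without untreated replicate 1 or 3 or letrozole replicate 2 or 3, and the lymph node stroma score without untreated replicate 1 or 2 or letrozole replicate 2 or 3 (limma adjusted p up to 0.15). The count was 3438 and 752 without untreated replicates 1 and 2, and 623, 285 and 797 without letrozole replicates 1, 2 and 3. Without letrozole replicate 2, 2 milk protein, 2 epithelial, 6 proliferation and 0 T and NK cell genes passed in limma, and of the genes named with values Mki67, Ccna2, Rspo1, Gata3, Aldh1a1, Rps2 and Rpl34 kept their calls. Without untreated replicate 2, Csn2, Wap, Lalba, Nr4a1, Dusp1 and the genes named without values lost their calls, as did Lalba, Wap, Csn3, Trf, Clu, Calca, Tnfsf11, Klf4 and Zfp36 without letrozole replicate 1 and Wap, Calca, Tnfsf11, Klf4 and Zfp36 without letrozole replicate 3. Calca, Tnfsf11 and Zfp36 also lost theirs without untreated replicate 3 (limma adjusted p up to 0.91 over the alternatives of the genes named, with the tissue covariates for Krt8).

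In the CYP19A1 line 4 genes fell with letrozole and 0 rose (limma, with 733 at unadjusted p under 0.05). Tmed3, a vesicle trafficking gene, stood at 23.6 ± 4.71 against 57.4 ± 10.1 TPM (-1.25 ± 0.19, n = 3 each), and Aoc1, a diamine oxidase gene, fell by 1.95 ± 0.32. The others were the microRNA gene Mir7034, listed at 0 in all 3 letrozole libraries, and 9530014B07Rik, named after its value was seen (limma adjusted p = 0.032 for the first 3). The values of Mir7034, a small RNA gene, are uncertain. Areg stood at 1.19 ± 0.656 against 18.4 ± 8.35 TPM and Pgr differed by -1.90 ± 0.39, and neither passed (limma adjusted p = 0.13 and 0.20). Of 12 hormone-sensing luminal genes 0 passed over all genes in limma and 7 were lower adjusted over the list alone. Their score fell by 0.93 ± 0.24 (limma adjusted p = 0.031, and up to 0.33 with a library left out, where it passed without letrozole replicate 3 alone), and camera from limma gave adjusted p = 8.2e-10, or adjusted p = 0.17 with an estimated correlation. The epithelial score differed by -0.91 ± 0.39 (limma adjusted p = 0.26, and camera adjusted p = 0.69 with an estimated correlation), with 5 genes lower adjusted over the list alone. Median-ratio scaling gave 1 higher and 8 lower genes. The count was 0 in limma without untreated replicate 2 or 3, without letrozole replicate 1 or 3, with the tissue covariates or with no filter, and limma adjusted p reached 0.27 for Tmed3 and 0.71 for Aoc1 over the alternatives.

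Averaged over the lines, letrozole lowered epithelial and hormone-sensing genes. Of 14 epithelial genes 11 fell (13 adjusted over the list alone), with Krt8 at -1.61 ± 0.29 and Krt19 at -1.57 ± 0.28 and the score at -1.29 ± 0.28 (limma adjusted p = 0.0029). Of 12 hormone-sensing genes 4 fell (8 adjusted over the list alone), namely Areg (-2.10 ± 0.42), Gata3 (-1.19 ± 0.22), Pgr (-1.15 ± 0.28) and Prlr, the prolactin receptor (-1.04 ± 0.25). The hormone-sensing score fell by 0.82 ± 0.17 (limma adjusted p = 0.0029). Of 20 proliferation genes 10 fell (20 adjusted over the list alone), with the score at -0.80 ± 0.18 (limma adjusted p = 0.0030), and of 15 milk protein genes 4 fell (11 adjusted over the list alone), with the score at -2.39 ± 0.64 (limma adjusted p = 0.011). Camera from limma gave these 4 lists adjusted p = 0.58 with an estimated correlation. The lymph node stroma score also differed in this average, by -0.67 ± 0.21 (limma adjusted p = 0.035). It lost its call without Esr1 untreated replicate 1 or Esr1 letrozole replicate 2 or 3. Its call also ended without CYP19A1 untreated replicate 1 or 2 or CYP19A1 letrozole replicate 1 (limma adjusted p up to 0.11). Zbtb16 (1.23 ± 0.26) and Tsc22d3 (1.14 ± 0.21), both glucocorticoid-induced genes, rose (limma adjusted p = 0.025 and 0.020), as did Aldh1a1 by 1.20 ± 0.28.

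That average gave 75 higher and 548 lower genes (623 in limma, and 3797 at unadjusted p under 0.05), 839 and 1058 after median-ratio scaling, 539 and 1265 after rescaling without the most abundant genes, and 0 in limma with the tissue covariates. The epithelial covariate itself fell with letrozole in this average, so that 0 does not decide on tissue share. In the Esr1 line the count was 1158, 402 and 95 without untreated replicates 1, 2 and 3 and 115, 1 and 225 without letrozole replicates 1, 2 and 3. In the CYP19A1 line it was 7 and 0 without untreated replicates 1 and 2 and 2 and 415 without letrozole replicates 1 and 2. Every gene named for the average lost its call without Esr1 letrozole replicate 2, CYP19A1 untreated replicate 1 or 2 or CYP19A1 letrozole replicate 1 (limma adjusted p up to 0.55 over the alternatives). Without Esr1 untreated replicate 3, Areg, Pgr, Prlr and Aldh1a1 did too, as did Pgr, Prlr and Aldh1a1 without Esr1 letrozole replicate 1 or 3, Aldh1a1 without Esr1 untreated replicate 2 and Prlr without CYP19A1 letrozole replicate 2.

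The response to letrozole was not shown to differ between the lines in the fit of all samples, although its calls were far more numerous in the Esr1 line. The interaction gave 0 genes in limma (2277 at unadjusted p under 0.05), with Cd300ld3 closest at -2.42 ± 0.40 (limma adjusted p = 0.084) and Csn2 at 9.18 ± 3.00 (limma adjusted p = 0.32). The milk protein score had an interaction of 3.30 ± 1.28 and the proliferation score of 1.00 ± 0.36 (limma adjusted p = 0.19 for both, and camera adjusted p = 0.43 with an estimated correlation). The count was 23 without Esr1 untreated replicate 1 and 1 without CYP19A1 untreated replicate 1, and it was 681 with sample weights, 77 with only the compared groups fitted, 38 with the muscle covariate and 9 with no filter.

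Some of the genes named above as raised by tamoxifen also differed between the drugs, though how many did so was not counted. In the Esr1 line Mmd2 (4.01 ± 0.28), Pcp4 (2.76 ± 0.50) and Fam78b (2.41 ± 0.40) were higher with tamoxifen than with letrozole, and Cd300ld3 was lower (-1.83 ± 0.28, limma adjusted p from 1.2e-07 to 0.025). In the CYP19A1 line Akr1cl was higher by 7.11 ± 0.72, Mmd2 by 5.02 ± 0.28, Aqp5 by 3.55 ± 0.62, Oxtr by 3.05 ± 0.58 and Thbs2 by 2.86 ± 0.52 (limma adjusted p from 1.9e-09 to 0.026). Of 14 epithelial genes 0 passed in limma in the Esr1 line and 13 were higher with tamoxifen adjusted over the list alone. Their score differed by 1.12 ± 0.39 (limma adjusted p = 0.33), and camera from limma gave adjusted p = 3.3e-11, or adjusted p = 0.91 with an estimated correlation. Of 17 extracellular matrix genes Thbs2 alone passed in the CYP19A1 line, with 4 higher adjusted over the list alone (camera from limma, adjusted p = 0.00038, and adjusted p = 0.98 with an estimated correlation).

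These contrasts gave 19 higher and 6 lower genes in the Esr1 line (25 in limma, and 1475 at unadjusted p under 0.05). There were 47 and 1 in the CYP19A1 line (48 in limma, and 1950 at unadjusted p under 0.05), where the median of all genes was 0.162 log2 and -0.000304 after median-ratio scaling. The Esr1 count was 62, 9 and 103 without tamoxifen replicates 1, 2 and 3 and 16, 9 and 14 without letrozole replicates 1, 2 and 3, and the CYP19A1 count was 28 and 21 without tamoxifen replicates 1 and 2 and 24 without letrozole replicate 1. In the Esr1 line Pcp4, Fam78b and Cd300ld3 lost their calls without tamoxifen replicate 2, and Pcp4 and Fam78b without any letrozole replicate (limma adjusted p up to 0.33). In the CYP19A1 line Aqp5, Oxtr and Thbs2 lost theirs without any tamoxifen replicate, Aqp5 and Thbs2 without letrozole replicate 1 and Thbs2 without letrozole replicate 3 (limma adjusted p up to 0.27), while Akr1cl and Mmd2 kept theirs under every alternative there.

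**Figure D4:**
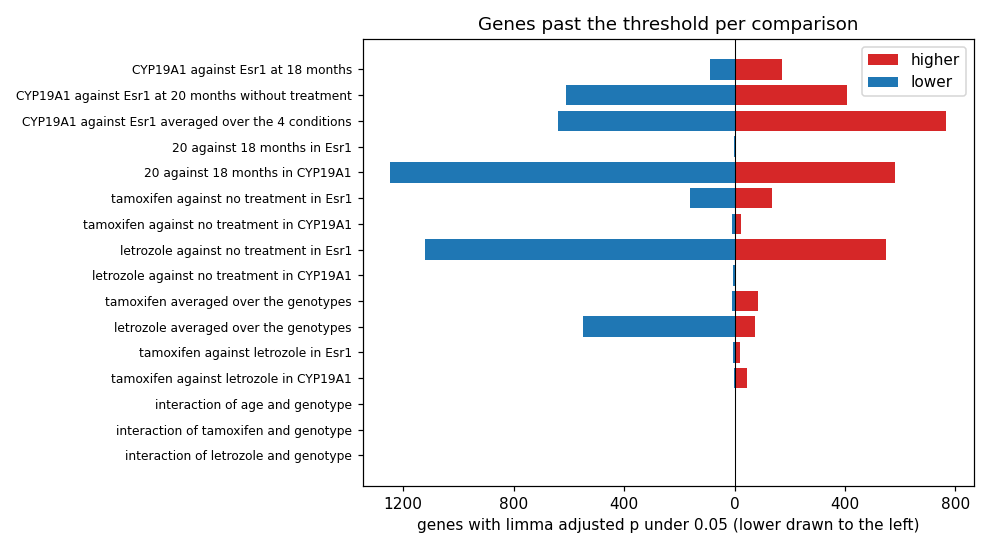
Number of genes that passed in limma (adjusted p under 0.05), higher to the right and lower to the left of the line, in each of the 16 comparisons. The counts ran from 0 for the tamoxifen and letrozole interactions to 1827 for age in the CYP19A1 line.

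The remaining lists held few changed genes. In the averaged line comparison the interferon response genes Ifit3 (-1.08 ± 0.17) and Ifit1 (-0.57 ± 0.15) were lower in CYP19A1 glands among 18, as were Hsd17b7 (-0.78 ± 0.11) among 21 cholesterol synthesis genes and the B cell receptor gene Cd22 (-0.75 ± 0.18) among 12. Of these 4, Ifit1 alone lost its call, with the tissue covariates (limma adjusted p = 0.11, the highest over its alternatives). The plasma cell list gene Fkbp11 fell by 2.40 ± 0.44 with letrozole in the Esr1 line, and the plasma cell score fell by 0.62 ± 0.21 in the average over lines (limma adjusted p = 0.040, and camera adjusted p = 0.58 with an estimated correlation). With a library left out that score passed only without Esr1 untreated replicate 2, Esr1 letrozole replicate 1 or CYP19A1 letrozole replicate 2 (limma adjusted p up to 0.11). Of the 14 macrophage and 4 tested neutrophil genes 0 passed in limma in any comparison. The macrophage and neutrophil scores, over 14 and 10 genes, differed between the lines by -0.17 ± 0.15 and -0.07 ± 0.09 on average (limma adjusted p = 0.46 and 0.63). Average scores differed by 0.08 ± 0.05 for steroid metabolism (15 genes, 11 tested) and 0.12 ± 0.14 for nerve and Schwann cells (9 genes). They differed by 0.01 ± 0.11 for senescence-associated secreted genes (15 genes, 10 tested) and -0.31 ± 0.11 for keratinocytes (12 genes, 3 tested). These 4 scores had limma adjusted p = 0.27, 0.54, 0.98 and 0.082. With tamoxifen in the Esr1 line the scores of 14 circadian clock and 13 mitochondrially encoded genes differed by 0.48 ± 0.20 and 0.64 ± 0.28 (limma adjusted p = 0.24 for both). Camera from limma called both there (adjusted p = 0.013 and 0.00079, and adjusted p = 0.75 with an estimated correlation). With letrozole averaged over the lines 3 of 21 tested oestrogen-responsive genes fell, and 5 adjusted over the list alone. Without Esr1 untreated replicate 3, 0 of them passed over all genes in limma. The score of that list, over 25 genes, differed by -0.24 ± 0.11 (limma adjusted p = 0.14, and camera adjusted p = 0.76 with an estimated correlation).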

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

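The interaction test and the comparison with other splits of the samples were both planned, and no test in this part was chosen after its result was seen. Gstp-ps, a processed pseudogene of a glutathione S-transferase, stood out because its change with age differed between the lines in the interaction test (1.86 ± 0.28 on the log2 scale, limma adjusted p = 0.031). In CYP19A1 glands it stood at 3.01 ± 0.432 TPM (SD, n = 3) at 18 months and 11.5 ± 2.87 TPM at 20 months, then 8.07 ± 0.986 TPM with tamoxifen and 9.04 ± 1.03 TPM with letrozole. In Esr1 glands it stood at 1.15 ± 0.329 TPM at 18 months, 0.860 ± 0.522 TPM at 20 months and 1.27 ± 0.271 TPM with letrozole. Over the alternatives the interaction ranged from 1.60 to 2.44 and its adjusted p in limma reached 0.53. Its call ended with a pseudocount of 0.1, with the replicate number as a block and with only the compared groups fitted. It also ended without Esr1 18-month replicate 2, CYP19A1 18-month replicate 1 or 2, or CYP19A1 20-month replicate 2 or 3. Pseudogenes share reads with their parent genes, so the value is uncertain.

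Other splits of the same samples were counted for each of the 16 gene counts, with 100 drawn where there were more than that. For the lines averaged over the 4 conditions, the real grouping gave 1404 genes and the highest other split 19. Only the real grouping, 1 of 100 splits, reached the real count, a share under the preset limit of 0.05. Tamoxifen averaged over the lines gave 95 genes against 25 at most in another split, again 1 of 100. For letrozole averaged over the lines 2 of 100 splits, the real one among them, reached the real count of 623. The higher one, with 971 genes, kept the real grouping of the Esr1 samples and mixed the CYP19A1 samples. The share for this average was under the limit too, but the Esr1 samples can carry the count, which fell to 0 without CYP19A1 untreated replicate 2. For the interaction with age chance could not be excluded, since 34 of 100 splits reached its single gene. For the interactions with tamoxifen and letrozole the real count was 0 in limma (2021 and 2277 at unadjusted p under 0.05), which all 100 splits reach by construction, so the comparison says nothing there. The highest other splits of the 3 interactions gave 4658, 500 and 1321 genes. Each of these kept the real grouping in 1 line, in either direction, and mixed the other, so that the difference between the real groups of that line enters the interaction by construction.

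With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The lines at 18 months gave 262 genes and another split 305, so that 2 of 10 reached the real count. That split set Esr1 replicate 1 and CYP19A1 replicates 1 and 3 against the others. Age in the Esr1 line gave 1 gene and another split 3, with 5 of 10 reaching the real count. In the others only the real grouping, 1 of 10, reached its count. The real and highest other counts were 1019 and 0 for the lines at 20 months, 1827 and 11 for age in the CYP19A1 line, 299 and 2 for tamoxifen and 1672 and 1 for letrozole in the Esr1 line. They were 31 and 2 for tamoxifen and 4 and 1 for letrozole in the CYP19A1 line, and 25 and 2 in the Esr1 line and 48 and 2 in the CYP19A1 line for tamoxifen against letrozole.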

How the results depend on the processing

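The muscle covariate, the fit without 3 libraries and the list score fit were chosen only after the data were seen, and the other alternatives were planned. All counts are genes that passed in limma at adjusted p under 0.05, and values are given where a count moved by more than 1.5 times. The cause was not tested for any of these moves, except where the construction of the alternative shows it. Sample weights moved all 16 counts, which were 871 for the lines at 18 months, 4504 at 20 months and 3348 on average, 719 for age in the Esr1 line and 4863 in the CYP19A1 line, and 925 for the age interaction. For tamoxifen they were 1469 in the Esr1 line, 566 in the CYP19A1 line, 1400 on average and 624 for the interaction. For letrozole they were 7957, 10, 4791 and 681 in the same order, and for tamoxifen against letrozole 120 and 220 in the Esr1 and CYP19A1 lines.

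Median-ratio scaling gave 2854 genes for the lines at 20 months, 2259 on average, 5 for the age interaction, 1881 and 219 for tamoxifen in the Esr1 line and on average, 8 for the tamoxifen interaction, 4111, 9 and 1897 for letrozole in the Esr1 line, in the CYP19A1 line and on average, 1 for the letrozole interaction and 56 for tamoxifen against letrozole in the Esr1 line. Rescaling without the most abundant genes gave 2542, 2203, 1563, 185, 1, 3796 and 1804 genes for the lines at 20 months and on average, tamoxifen in the Esr1 line, on average and in its interaction, and letrozole in the Esr1 line and on average, and 50 for tamoxifen against letrozole in the Esr1 line. With a pseudocount of 0.1 there were 0 genes for age in the Esr1 line, 190 and 18 for tamoxifen in the Esr1 and CYP19A1 lines, 1 for letrozole in the CYP19A1 line, 13 for tamoxifen against letrozole in the Esr1 line and 0 for the age interaction. With no filter there were 4 and 1091 genes for age in the Esr1 and CYP19A1 lines, 8, 4 and 9 for the age, tamoxifen and letrozole interactions, 0 and 98 for letrozole in the CYP19A1 line and on average, and 58 for tamoxifen against letrozole in the Esr1 line.

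With the epithelial and B cell scores as tissue covariates there were 482, 1888 and 3200 genes for the lines at 18 months, at 20 months and on average, 2 for age in the Esr1 line, 866 and 319 for tamoxifen in the Esr1 line and on average, 0 for letrozole in either line and on average, and 6 for tamoxifen against letrozole in the Esr1 line. For letrozole in the Esr1 line and on average the epithelial score itself fell, so the 0 counts there do not decide on tissue share. The balance moved with the tissue covariates, to 1352 higher and 536 lower for the lines at 20 months, 2584 and 616 on average, 613 and 253 for tamoxifen in the Esr1 line and 603 and 739 for age in the CYP19A1 line. It moved the other way with sample weights (1045 and 3459 for the lines at 20 months and 289 and 1180 for tamoxifen in the Esr1 line) and without the 3 libraries in doubt (274 and 1124, then 77 and 426). With the muscle covariate there were 1964 genes for the lines at 20 months, 4382 for age in the CYP19A1 line, 1136 and 201 for tamoxifen in the Esr1 line and on average, 2986 and 1865 for letrozole in the Esr1 line and on average, and 83, 43 and 38 for the age, tamoxifen and letrozole interactions. Without the 3 libraries in doubt there were 0 and 4812 genes for age in the Esr1 and CYP19A1 lines, 503, 53 and 171 for tamoxifen in the Esr1 line, the CYP19A1 line and on average, 19 and 2173 for letrozole in the CYP19A1 line and on average, 44 and 130 for tamoxifen against letrozole in the Esr1 and CYP19A1 lines, and 57, 3 and 7 for the age, tamoxifen and letrozole interactions. With only the compared groups fitted, which leaves fewer samples to estimate the spread, there were 144 and 428 genes for the lines at 18 and 20 months, 6 and 163 for age in the Esr1 and CYP19A1 lines, 6 and 147 for tamoxifen in the Esr1 and CYP19A1 lines, 824 for letrozole in the Esr1 line, 1 for tamoxifen against letrozole in the Esr1 line, and 4 and 77 for the age and letrozole interactions.

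The replicate numbers do not pair the samples. Of 84 pairs with the same number 19 had a correlation of deviations above 0.1, with values from -0.41 to 0.30, against 31 of 168 pairs with different numbers, from -0.40 to 0.55. With the replicate number as a block the count was 0 for letrozole in the CYP19A1 line and 0 for the age interaction, and no other count moved by more than 1.5 times. Of the 32 lists in 16 comparisons camera from limma made 179 calls, between 152 and 201 under the other settings fixed in advance with the preset correlation, 0 with an estimated correlation and 21 in the list score fit.

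With 1 library left out at a time the counts ranged from 175 to 223 for the lines at 18 months, 256 to 1941 at 20 months and 1158 to 1665 on average. They ranged from 0 to 17 for age in the Esr1 line, 2 to 2283 in the CYP19A1 line and 0 to 47 for the age interaction. For tamoxifen they ranged from 42 to 1188 in the Esr1 line, 15 to 27 in the CYP19A1 line, 67 to 437 on average and 0 to 6 for the interaction. For letrozole they ranged from 285 to 3438 in the Esr1 line, 0 to 3 in the CYP19A1 line, 0 to 1158 on average and 0 to 23 for the interaction. For tamoxifen against letrozole they ranged from 9 to 103 in the Esr1 line and 21 to 42 in the CYP19A1 line. A group left with 2 samples drew its spread from all groups. The log2 difference of Esr1 between the lines ranged from -0.017 to 0.093.

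Of 1116 values of named genes and list members, those that kept their direction and their side of the threshold numbered 1041 with a pseudocount of 0.1, 925 with no filter, 994 with median-ratio scaling, 944 of 1045 with rescaling, 924 with sample weights, 1050 with the block, 851 with the tissue covariates, 1030 with the muscle covariate, 1000 without the 3 libraries, 821 of 1032 with only the compared groups and 8441 of 10182 with 1 library left out. Of the remaining values, 1 changed sign with sample weights and 9 with the tissue covariates. The mitochondrial gene mt-Co2 turned to 1.43 for age in the Esr1 line with sample weights, and the cause was not tested. With the tissue covariates letrozole in the Esr1 line gave Epcam at 0.02, Grhl2 at 0.25, Krt18 at 0.12, Krt19 at 0.30 and Sox10 at 0.11, and letrozole on average gave Krt14 at 0.01, Ehf at 0.04, Epcam at 0.11 and Spint2 at 0.14. Of these genes all but Sox10 and Krt14 are members of the epithelial list whose score is the covariate, which removes their shared change by construction. TPM keeps no read depth, so how far depth limits the low genes is unknown.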

Other observations

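The criterion of the salivary gland test was written before the result of that test was seen. All other tests of explanations in this part were chosen only after the result was seen. Averaged over the conditions, Iglc1, an immunoglobulin lambda constant gene, was lower in CYP19A1 glands by -3.09 ± 0.38 and alone passed among 13 plasma cell genes (limma adjusted p = 2.4e-05). The plasma cell score differed by -0.17 ± 0.15 (limma adjusted p = 0.45). Ccl21a, a lymphoid chemokine gene, was lower by -1.39 ± 0.30 with 1 other of 9 tested lymph node stroma genes (limma adjusted p = 0.0057), and the score of that list differed by -0.50 ± 0.15 (limma adjusted p = 0.056). The MHC class II pseudogene H2-Ea-ps was higher by 3.17 ± 0.36 and Stc2, stanniocalcin 2, by 0.84 ± 0.17 (limma adjusted p = 7.8e-06 and 0.0029). Iglc1, Ccl21a, H2-Ea-ps and Stc2 kept their calls under every alternative run. Il33, a cytokine of stromal and epithelial cells, rose by 1.56 ± 0.32 with age in the CYP19A1 line (limma adjusted p = 0.014), but not without 18-month replicate 1 or 20-month replicate 3 (up to 0.093 over the alternatives). With letrozole in the Esr1 line Fasn (-2.06 ± 0.55), Acaca (-1.61 ± 0.46) and Srebf1 (-1.26 ± 0.27) fell among 15 genes of fatty acid synthesis, with 5 lower and 1 higher adjusted over the list alone. Their score differed by -0.51 ± 0.37 (limma adjusted p = 0.35), camera from limma gave adjusted p = 0.087, or adjusted p = 0.70 with an estimated correlation, and 0 of them passed in limma without letrozole replicate 2 or with the tissue covariates.

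A set of 95 genes differed between the lines by at least 2-fold on average with no overlap between the 12 and 12 libraries. Pseudogenes were 43 of the 95, or 45.3%, against 7.59% of the tested genes (Fisher's exact test, one-sided p = 1.7e-23), so reads traded between near-identical copies may account for part of the set. Of the 81 genes with a position 33.3% had another of the set within 2 Mb, against a median of 19.8% in 10000 random sets (permutation p = 0.02), but the largest letrozole changes reached 42.0%, which by the criterion as first written counted against blocks of chromosome that differ between the lines. That reading was changed to undecided after the result was seen, because the letrozole genes include neighbouring families such as the caseins, and the 43 positioned genes of the set that are not pseudogenes, a subset also chosen afterwards, reached 46.5% against a median of 9.30% (permutation p = 0.0001, the smallest these sets can give). Zfp966, Zfp967 and Zfp973 on chromosome 2 (175275125 to 176927813, with 8 genes of the set) and Ifi213, Mndal, Ifi202b and Ifi205 on chromosome 1 (173566280 to 174031755) were the main neighbours. These are neighbouring families too, which the random sets do not match, so the share of 46.5% does not decide for blocks either. Different genetic backgrounds of the lines remain a hypothesis that cannot be told apart from the transgenes, since every library of a line carries both.

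The fall of epithelial genes with letrozole was -1.29 ± 0.28 in the averaged score. It remained after rescaling without the most abundant genes (-1.34 ± 0.29), which argues against a few abundant transcripts as the whole cause. With the muscle score as a covariate it was -1.37 ± 0.27. That fit cannot decide on muscle, since Esr1 18-month replicate 1 and CYP19A1 18-month replicate 3 (muscle scores 3.38 and 1.38) largely set its slope. In the Esr1 line every letrozole library had a higher muscle score than every untreated library. The basal score fell less than the epithelial score, by a difference of 0.83 ± 0.21, and the milk protein score fell more, by -1.10 ± 0.50, which by the criterion as first written counted against a loss of every kind of epithelial cell alike. However, the luminal progenitor score also fell less, by a difference of 0.61 ± 0.15, and the hormone-sensing score differed by 0.46 ± 0.23. Lists of luminal cells thus differ from the epithelial score too, and several basal genes are also made by the smooth muscle of vessels, so that reading was changed to undecided after the result was seen. A smaller share of epithelial cells and lower expression within them may each contribute and cannot be told apart.

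Tamoxifen raised 16 genes in both lines, and Aqp5, an aquaporin of secretory glands, in their average, so salivary gland tissue was weighed as a candidate source. The salivary gland score over 12 genes, of which 1 was abundant enough to be tested singly, differed by -0.02 ± 0.05, Smr3a, Dcpp1 and Dcpp3 were listed at 0, and Amy1 stood at 62.7 ± 15.3 TPM with tamoxifen and 55.7 ± 22.6 TPM without (SD, n = 6 each), which argues against that source. All 16 genes passed in the average with the tissue covariates and all 16 with the muscle covariate. They were picked for passing in both lines, which makes it hard for these fits to remove their calls. The epithelial score was 4.47 against 5.02 in the Esr1 line and 4.28 against 4.38 in the CYP19A1 line, and the B cell score 1.98 against 1.96 and 1.60 against 1.77. These fits could hardly remove the calls, so they do not decide on a shift in the share of epithelium, B cells or muscle. An action of tamoxifen on gene expression in the gland stays open as a hypothesis that was not tested, as do shifts in these tissues, and changes in other cell types were not tested.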
